A study of Mus musculus with 10 samples.

How the data were processed

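RNA of lymphatic endothelial cells sorted by flow cytometry from MT-ret melanomas of 10 mice was sequenced, 5 mice per treatment, with 1 library per mouse. Per the labels, RNA was isolated with the PicoPure kit, full-length cDNA was made from 0.5 ng of RNA with the SMART-Seq v4 kit, which does not mark the strand, and libraries were built with the NEBNext ChIP-Seq kit. Groups were taken from the treatment label. The series design states independent biological replicates, so the spread between libraries includes that between mice. STAR, featureCounts and DESeq2 were used with the mm10 genome, per the submitters' processing notes; versions, annotation release and strand setting were not given in the sources used here.

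A single table covered all libraries. Per the file headers, it holds raw gene counts for each library, as the authors deposited them, and these counts were the input of every test. The authors also deposited FPKM per library, which matched the counts divided by exon length and by a library total without genes of the mitochondrial, X and Y chromosomes and rRNA genes; FPKM entered no test. The deposited TPM values were treated as a relative score, since their sum per library exceeded the total that defines TPM, and served only as an alternative for the marker sums. The authors deposited a mean of scaled counts (baseMean), a signal that was used only to check the file. The deposited log2 fold changes and p-values are those of the authors, and low-count genes lie near 0 in them, as shrunken estimates do. Of 23510 rows, 8 had a count of 0 in every library and 23435 had an ID in GENCODE release M21 of the mm10 assembly, from which coordinates were taken. A symbol was shared by 2 rows in 29 cases. In 29 of these rows the deposited mean differed by over 2% from the counts, so deposited statistics of repeated symbols were not used; in all other rows the difference was at most 0.0038%. There were 0 unused columns of values per sample.

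Library totals ran from 38090933 to 83850341 counts. The rRNA share and 4 other library measures were compared between the groups with a two-sided exact permutation test. Mitochondrial genes took 0.477% to 0.917% of counts, rRNA genes 0.227% to 0.422% and the 100 most abundant genes 17.5% to 19.4%. At this depth the spread between libraries exceeded counting error. With 1 library per mouse, that of mice cannot be separated from that of sorting and cDNA amplification. Reads carry no molecular identifiers. No pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom 55.1). Correlations of log2 CPM were 0.936 to 0.965 within IgG, 0.924 to 0.971 within anti-Ang2 and 0.924 to 0.956 between the groups. The first 3 principal components took 23.6%, 17.3% and 12.7% of the variance. Anti-Ang2 5 stood apart on the second (102.5, the others -35.7 to 34.1) and anti-Ang2 4 on the third (75.8, the others -44.1 to 42.0). Their quality weights were the lowest (0.417 and 0.606, the others 0.911 to 1.43). The labels name no batch.

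Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided, TMM normalization, filterByExpr with a minimum count of 10 and a minimum total of 15, treatment as the only factor) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the standard error was derived from the same test. CPM are scaled by TMM, and log2 CPM used a prior count of 2. Gene lists written from textbook knowledge were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated per list and with fry beside it, adjusted over the 27 pathway lists and separately over the 6 cell type lists with at least 5 tested members. With fry, 9 pathway lists passed its directional test, which compares no list with other genes. Of the lists called by camera, G2/M (fry adjusted p = 0.0824), hypoxia (0.316) and cholesterol synthesis (0.232) did not pass it. The angiopoietin-Tie, pro-apoptotic, junction and flow-responsive lists passed fry (adjusted p 0.0442 to 0.0444) but not camera. Summed CPM of each marker list were compared with a two-sided exact permutation test over all 252 arrangements of 5 against 5 libraries (smallest p 0.00794). The marker list of pericytes shares Notch3 with the Notch list and that of keratinocytes shares Perp with the p53 list; the other marker lists share no gene with another list. Other tools were Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and DESeq2 1.42.0.

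The tests were tried in a single run on simulated data with the means, library sizes and edgeR gene dispersions of these 10 libraries. Among the 15665 simulated genes that passed the filter, edgeR recovered 37.3%, 70.1% and 93.9% of genes changed by 1.5-fold, 2-fold and 4-fold, and 2.9% of its calls were false. Limma-voom had 5% false calls, and DESeq2, run on all 16240 simulated genes without that filter, had 28%. As the counts were drawn with the dispersions of edgeR, these shares do not give the false calls of each tool in the real data. Camera found a list of 30 genes raised by 1.3-fold and called 1 of 20 unchanged lists. The simulated genes varied independently, while the estimated correlation in the lists called from the real data reached 0.68. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes.

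The genes named in the text follow a rule set, like the lists, the main tests and most alternatives, before the data were examined. It takes Angpt2, Tek and Tie1; the 12 higher and 12 lower called genes with the smallest p, a mean log2 CPM of at least 2 and a symbol that is not a predicted model; up to 4 members of each pathway list with the smallest p; and up to 3 markers of each cell type with the highest CPM. After the results were seen, fewer than these were named: members that did not pass were mostly left out, 1 gene is not reported here, and markers were named only for melanoma cells, macrophages, pericytes, fibroblasts and dendritic cells. That choice was made with the number of direction changes under other settings in view, which were more frequent among the weakly expressed markers left out. Prox1, Lyve1 and the genes first named under the other observations, Thbs1 among them, lie outside the rule and were chosen after their values were seen.

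Alternatives were DESeq2, limma-voom, limma with library quality weights, other normalizations, no or a stricter filter (50 counts in 5 libraries), robust dispersion, an adjusted p under 0.10, the replicate number as a block, the log2 macrophage or melanoma marker sum as a covariate, and leaving out each library. After the data had been seen, 3 were added: both marker sums as covariates, removal of the 3 libraries with the highest melanoma marker sum, and an exact permutation of the mean log2 CPM of each list. The removal keeps only anti-Ang2 4 and 5 beside the IgG libraries.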

Results

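Lymphatic endothelial cells (LEC), the cells that line lymphatic vessels, were sorted from MT-ret melanomas, a mouse melanoma grown from implanted fragments, and profiled by RNA sequencing. The mice had received an antibody against angiopoietin-2 (Ang2), a secreted ligand of the endothelial receptor Tie2, or control IgG 12 hours before they were killed. Each treatment had 5 mice and each mouse gave 1 library made from 0.5 ng of RNA, so that n = 5 per group unless libraries were left out. The IgG libraries held 40313230, 83850341, 41718067, 41177761 and 40852634 gene counts. The anti-Ang2 libraries held 51125867, 50594990, 51786044, 50604006 and 38090933. Between 19201 and 21215 genes had at least 1 count in a library. Genes of rRNA took 0.3897 ± 0.0414% of counts in IgG and 0.3004 ± 0.0555% in anti-Ang2 libraries, of which 4 lay below every IgG library (two-sided exact permutation p = 0.0159, adjusted p = 0.0794 over 5 library measures). The question put by the series title was how the transcriptome of tumour LEC responds to acute inhibition of Ang2.

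Anti-Ang2 raised the transcript of its own target and lowered those of both Tie receptors. Angpt2, which encodes Ang2, rose from 769 ± 279 to 3222 ± 534 CPM (counts scaled to library size; mean ± SD, n = 5). Its log2 fold change was 2.07 ± 0.22 (SE), with an adjusted p of 0.00100 by edgeR. Tek, which encodes Tie2, fell from 503 ± 88.7 to 202 ± 38.5 CPM (log2 fold change -1.31 ± 0.16, adjusted p = 0.00116 by edgeR). Tie1, the related receptor that forms complexes with Tie2, fell from 1519 ± 199 to 1067 ± 72.4 CPM (log2 fold change -0.51 ± 0.10, adjusted p = 0.0140 by edgeR). In all 3 genes the 5 anti-Ang2 libraries lay on the same side of every IgG library. In mm10, Angpt2 (ENSMUSG00000031465.6) lies on the minus strand of chromosome 8 from 18690263 to 18741562. Tek (ENSMUSG00000006386.15) lies on the plus strand of chromosome 4 from 94739289 to 94874976, and Tie1 (ENSMUSG00000033191.14) on the minus strand of chromosome 4 from 118471191 to 118490061. Each span covers the whole annotated gene, exons, introns and untranslated regions included. The summed CPM of 12 melanoma cell markers was 984 ± 767 in IgG and 3405 ± 1905 in anti-Ang2 libraries, and that of 15 macrophage and monocyte markers 57.6 ± 66.2 and 149 ± 93.7. The log2 fold change of Tie1 was -0.44 ± 0.14 with the melanoma sum as a covariate (adjusted p = 0.202) and -0.40 ± 0.12 with the macrophage sum (0.192), the effect being smaller and the SE wider. Without the 3 libraries of highest melanoma sum (anti-Ang2 1, 2 and 3) it was -0.56 ± 0.14 (0.0955), the effect being no smaller and the SE wider. That fit keeps only anti-Ang2 4 and 5 beside the IgG libraries, and their quality weights were the lowest (0.606 and 0.417). A call kept or lost in it, here and below, therefore does not isolate the part of melanoma RNA. Angpt2 and Tek passed with either sum and without anti-Ang2 1, 2 and 3, but not with both sums as covariates, where 0 genes passed by edgeR. Of the 21 tested genes of the angiopoietin-Tie list, Angpt2 alone rose and 4 fell (adjusted over the list alone, 1 and 6). Beside Tek and Tie1, these were the adaptor Shc1 (-0.66) and the PI3-kinase subunit Pik3r1 (-0.68). The list as a whole did not pass (camera adjusted p = 0.234). Shc1 went from -0.66 ± 0.10 to -0.62 ± 0.14 with the melanoma sum (adjusted p = 0.0810) and to -0.60 ± 0.12 with the macrophage sum (0.0546), and Pik3r1 from -0.68 ± 0.11 to -0.69 ± 0.15 with the macrophage sum (0.0727).

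Over the transcriptome, 217 genes were higher and 454 lower after anti-Ang2 among 16240 tested (edgeR, adjusted p under 0.05), of which 87 and 171 changed at least 2-fold. Among the genes with the smallest p, the matricellular growth factor Ctgf rose from 376 ± 94.5 to 1010 ± 136 CPM and fibronectin (Fn1) from 3139 ± 728 to 7272 ± 1006 CPM. The laminin-related netrin Ntn4 rose from 115 ± 27.3 to 285 ± 15.8 CPM, the Wnt antagonist Frzb from 3.57 ± 0.85 to 11.2 ± 1.46 CPM and the vasoactive peptide adrenomedullin (Adm) from 226 ± 45.7 to 583 ± 134 CPM (SD, n = 5 each). Elastin (Eln) fell from 923 ± 262 to 169 ± 34.8 CPM and the matricellular protein periostin (Postn) from 391 ± 177 to 19.3 ± 10.8 CPM. The sialic acid hydroxylase Cmah fell from 451 ± 156 to 43.8 ± 12.9 CPM, the retinol-binding protein Rbp7 from 9.74 ± 2.03 to 1.22 ± 0.19 CPM and Duoxa2, the maturation factor of dual oxidase 2, from 23.4 ± 9.47 to 2.52 ± 0.64 CPM. Other genes selected by the same rule rose by a log2 fold change of 0.65 (the zinc transporter Slc39a4) to 1.39 (the dynein heavy chain Dnah17). Between them lay the endotoxin co-receptor Cd14 at 1.26, Litaf at 0.96, Fam49a at 0.68 and the glutathione transferase Gstm1 at 0.99. Gstm1 belongs to a family of similar genes, so that its counts are uncertain. The remaining lower genes were the monocarboxylate transporter family member Slc16a12 (-1.94), Lynx1 (-2.39), Armc9 (-1.13), the glycosyltransferase Galnt18 (-1.39), the calcineurin inhibitor Rcan1 (-0.78), nucleoredoxin (Nxn, -1.62) and the kinesin Kif26b (-1.95). All genes of this rule, including Angpt2, had adjusted p of at most 0.00200 by edgeR. The groups did not overlap in 574 of the 671 called genes (85.5%), a high share being part of how they were selected. Over all tested genes the share was 6.10%, where chance gives 0.794%. Without 1 library the counts ranged from 82 to 326 higher and from 259 to 468 lower. The higher count was 117 without IgG 2, 82 without IgG 3, 131 without IgG 5, 131, 134 and 113 without anti-Ang2 1, 2 or 3, and 326 without anti-Ang2 5. The lower count was 292 without IgG 2 and 259 without IgG 3. On the first principal component anti-Ang2 5 lay at -25.0, among the IgG libraries (-72.4 to -7.33), and the other anti-Ang2 libraries at 21.3 to 65.4. DESeq2 called 810 higher and 880 lower. By edgeR 24 and 91 passed with the melanoma sum as a covariate, 28 and 114 with the macrophage sum, 0 and 0 with both sums (880 and 974 at an unadjusted p under 0.05), and 55 and 178 without anti-Ang2 1, 2 and 3. Fn1 (log2 fold change 1.21 ± 0.15 to 1.15 ± 0.23, adjusted p = 0.0514), Adm (1.37 ± 0.18 to 1.02 ± 0.22, 0.0650), Slc39a4 (0.65 ± 0.09 to 0.57 ± 0.12, 0.0562) and Fam49a (0.68 ± 0.09 to 0.65 ± 0.13, 0.0519) missed the threshold with the melanoma covariate. Frzb (1.65 ± 0.21 to 1.49 ± 0.29, 0.0543) did so without anti-Ang2 1, 2 and 3. The SE widened in each case, and the effect shrank most for Adm.

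**Figure D1:**
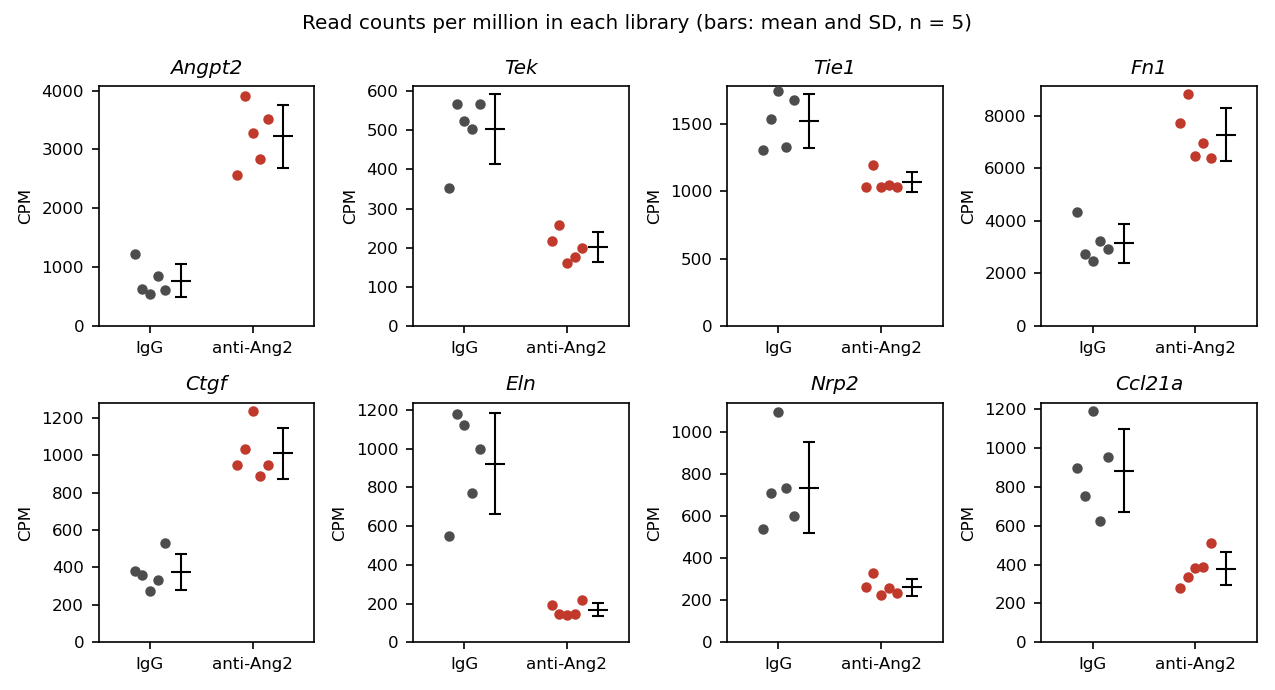
CPM of selected genes in each of the 5 IgG and 5 anti-Ang2 libraries (points), with the mean and SD of each group. Angpt2 rose from a mean of 769 to 3222 CPM and Tek fell from 503 to 202 CPM, with no overlap between the groups.

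**Figure D2:**
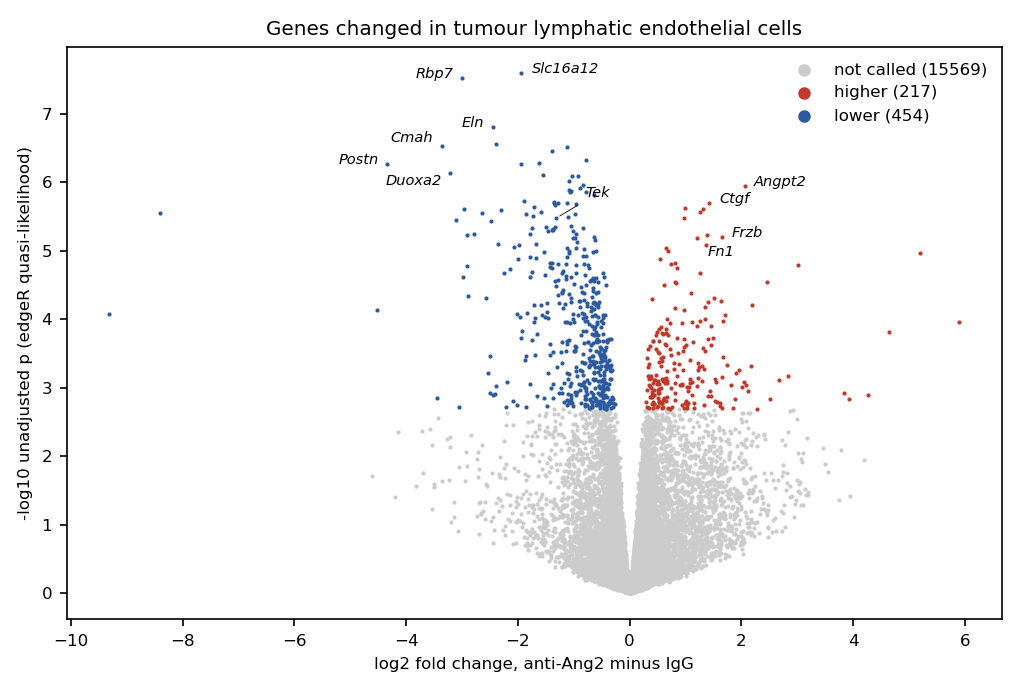
Log2 fold change (x axis, anti-Ang2 minus IgG) against -log10 unadjusted p of the edgeR test (y axis) for all 16240 tested genes, each point a gene. The 217 genes called higher are red and the 454 called lower are blue.

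Genes of the cell cycle were lower after anti-Ang2. Of 35 tested genes of G1/S transition and DNA replication, 9 fell and 0 rose (adjusted over the list alone, 21 fell and 0 rose), with a median log2 fold change of -0.58 (camera adjusted p = 3.8e-14; adjusted p = 0.205 with an estimated correlation). The transcription factor E2f2 fell from 29.7 ± 7.38 to 11.3 ± 2.20 CPM and thymidine kinase (Tk1) from 18.7 ± 2.88 to 7.71 ± 1.59 CPM. The replication checkpoint protein Clspn fell from 7.27 ± 1.70 to 2.43 ± 0.66 CPM and thymidylate synthase (Tyms) from 46.8 ± 5.30 to 31.3 ± 3.69 CPM (SD, n = 5 each). All 31 tested genes of G2/M and mitosis had a negative log2 fold change, with a median of -0.62 (camera adjusted p = 3.5e-09; adjusted p = 0.579 with an estimated correlation). Of these, 2 fell (adjusted over the list alone, 7), the mitotic kinesin Kif23 (-1.22 ± 0.25, SE) and the proliferation marker Mki67 (-0.88 ± 0.19). Kif23 missed the threshold without IgG 2, IgG 3 or anti-Ang2 1 (adjusted p up to 0.0577) and Mki67 without IgG 2, IgG 3, anti-Ang2 1 or anti-Ang2 3 (up to 0.0650). The melanoma marker sum, 984 CPM in IgG and 3405 CPM in anti-Ang2, moved in the opposite direction to these genes. Both lists still passed with the melanoma sum (camera adjusted p = 7.3e-16 and 0.00048) or the macrophage sum as a covariate (1.9e-13 and 2.6e-08). With the first the median of the G1/S list was -0.86 (median SE 0.20 before and 0.26 after) and that of the G2/M list -0.46 (0.28 and 0.37). With the second they were -0.62 (SE 0.27) and -0.64 (SE 0.35). Singly, E2f2 (-1.39 ± 0.19 to -1.21 ± 0.26, adjusted p = 0.0657), Clspn (-1.58 ± 0.26 to -1.81 ± 0.36, 0.0509), Tyms (-0.58 ± 0.11 to -0.59 ± 0.16, 0.133), Kif23 (to -1.07 ± 0.34, 0.209) and Mki67 (to -0.91 ± 0.27, 0.177) missed the threshold with the melanoma sum. All 5 missed it with the macrophage sum, E2f2 at -1.21 ± 0.25 (0.0551), Clspn at -1.55 ± 0.34 (0.0735), Tyms at -0.62 ± 0.14 (0.0859), Kif23 at -1.14 ± 0.31 (0.151) and Mki67 at -0.98 ± 0.23 (0.0929). The SE widened in every case, and the effect shrank most for E2f2 and Kif23. E2f2, Tyms, Kif23 and Mki67 also missed it without anti-Ang2 1, 2 and 3 (0.0585, 0.0900, 0.0721 and 0.110).

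Genes that mark the lymphatic lineage and its valves were lower as groups. Of 23 genes of lymphatic endothelial identity, 6 fell and 0 rose (adjusted over the list alone, 14 and 2), with a median log2 fold change of -0.42 (camera adjusted p = 1.4e-05; adjusted p = 0.205 with an estimated correlation). Nrp2, a co-receptor of VEGF receptor 3, fell from 735 ± 216 to 262 ± 40.5 CPM and the dendritic cell attractant Ccl21a from 883 ± 214 to 379 ± 85.9 CPM. The valve transcription factor Foxc2 fell from 263 ± 55.5 to 127 ± 26.3 CPM and the integrin Itga9 from 354 ± 22.2 to 164 ± 55.1 CPM (SD, n = 5 each). The lineage regulator Prox1 (1283 CPM in IgG and 1161 CPM in anti-Ang2, adjusted p = 0.495) and the hyaluronan receptor Lyve1 (4655 and 5646 CPM, adjusted p = 0.181) did not pass. Both were chosen after their values were seen. Of 19 genes of lymphatic valves and collecting vessels, 7 fell and 1, Fn1, rose (adjusted over the list alone, 9 and 1), with a median of -0.41 (camera adjusted p = 0.00034; adjusted p = 0.205 with an estimated correlation). The receptor kinase Ephb4 fell from 1042 ± 87.3 to 610 ± 49.8 CPM and its ligand Efnb2 from 449 ± 96.2 to 171 ± 31.9 CPM. Foxc2 and Itga9 belong to both lists. The identity list missed the threshold with both marker sums as covariates (camera adjusted p = 0.0508), its median going to -0.25 and the median SE of its genes from 0.15 to 0.18. Without anti-Ang2 1, 2 and 3 it passed (0.0322) with a median of -0.24 (SE 0.16). The valve list passed with the melanoma sum (0.0078) and with both sums (0.0308), its median going to -0.21 and -0.20 and the median SE from 0.17 to 0.21 and 0.22. The melanoma marker sum was 984 CPM in IgG and 3405 CPM in anti-Ang2 libraries. With it as a covariate, Foxc2 (log2 fold change -1.05 ± 0.17 to -0.83 ± 0.21, adjusted p = 0.111) and Ccl21a (-1.22 ± 0.19 to -0.68 ± 0.13, 0.0508) missed the threshold, Ccl21a through a smaller effect. With the macrophage sum Ccl21a was at -1.08 ± 0.22 (0.0542) and Itga9 went from -1.11 ± 0.21 to -1.29 ± 0.28 (0.0700). Without anti-Ang2 1, 2 and 3 Ccl21a was at -0.99 ± 0.25 (0.103) and Foxc2 at -0.87 ± 0.24 (0.128).

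Among receptors and signals of the vessel wall, members fell and rose without a call of their list by camera. In the Notch list, 5 of 24 genes fell and 0 rose (adjusted over the list alone, 6 and 3; camera adjusted p = 0.267). They included the ligand Dll1 (87 ± 23.6 to 25.9 ± 5.53 CPM), the sheddase Adam10 (-0.45), the ubiquitin ligase Dtx1 (-0.52) and the target gene Hey1 (-0.84). In the list of VEGF receptor 3 and growth factor signalling, Nrp2 and the VEGF receptor Kdr (1350 ± 228 to 777 ± 119 CPM) fell, and the feedback inhibitor Spry1 (1.02) and the receptor Igf1r (0.58) rose, among 26 genes (adjusted over the list alone, 10 rose and 5 fell; camera adjusted p = 0.175). In the list of flow-responsive and anticoagulant genes, thrombomodulin (Thbd, 673 ± 198 to 181 ± 34.7 CPM) and nitric oxide synthase (Nos3, 295 ± 108 to 110 ± 31.7 CPM) fell and endothelin (Edn1, 1.03) rose, among 21 genes (adjusted over the list alone, 5 fell and 2 rose; camera adjusted p = 0.655). In the TGF-beta and BMP list, Ctgf rose, and the ligand Tgfb3 (-0.84) and the decoy receptor Bambi (-0.82) fell, among 29 genes (adjusted over the list alone, 4 rose and 5 fell; camera adjusted p = 0.807). Of 22 genes of blood endothelial identity, the proteoglycan Esm1, found at vessel sprouts, rose (74.7 ± 21.8 to 204 ± 71.3 CPM), and the adhesion molecule Icam2 (-0.84) and Hey1 fell (adjusted over the list alone, 4 rose and 3 fell; camera adjusted p = 0.931). Adam10 and Nos3 missed the threshold without IgG 3 (Nos3 adjusted p = 0.0506). Hey1 (highest adjusted p without 1 library 0.0860), Spry1 (0.0798), Igf1r (0.126), Edn1 (0.109) and Bambi (0.0601) each missed it without any of 4 or more libraries. With the melanoma covariate the threshold was missed by Adam10 (-0.45 ± 0.09 to -0.50 ± 0.12, adjusted p = 0.106), Dtx1 (-0.52 ± 0.10 to -0.46 ± 0.15, 0.205), Hey1 (-0.84 ± 0.19 to -0.60 ± 0.24, 0.319), Kdr (-0.80 ± 0.14 to -0.73 ± 0.20, 0.139) and Nos3 (-1.42 ± 0.28 to -1.67 ± 0.37, 0.0772). So it was by Esm1 (1.45 ± 0.26 to 1.21 ± 0.32, 0.132), Icam2 (-0.84 ± 0.11 to -0.73 ± 0.15, 0.0601), Spry1 (1.02 ± 0.23 to 0.67 ± 0.31, 0.386), Igf1r (0.58 ± 0.15 to 0.59 ± 0.21, 0.251), Edn1 (1.03 ± 0.25 to 1.22 ± 0.33, 0.139) and Bambi (-0.82 ± 0.17 to -0.86 ± 0.23, 0.133). The SE widened in all 11, and the effect shrank most in Spry1 and Hey1. Each of these except Icam2 also missed it with the macrophage sum (0.106 for Esm1 to 0.347 for Hey1), where Nos3 was at -0.94 ± 0.34 (0.297), Dtx1 at -0.52 ± 0.13 (0.126) and Bambi at -0.57 ± 0.20 (0.301). Each except Esm1 and Edn1 missed it without anti-Ang2 1, 2 and 3 (0.0567 for Icam2 to 0.279 for Hey1; Dtx1 0.146), as did Dll1 (-1.75 ± 0.22 to -1.78 ± 0.35, 0.0530).

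FOXO target genes were higher as a group. Of 26 tested, 6 rose and 1 fell (adjusted over the list alone, 10 and 2), with a median log2 fold change of 0.33 (camera adjusted p = 0.00024; adjusted p = 0.205 with an estimated correlation). The risen genes included Angpt2, Esm1, the ubiquitin ligase Fbxo32 (16.7 ± 4.03 to 28.9 ± 3.71 CPM) and the transcription factor Klf6 (467 ± 51.9 to 644 ± 67.9 CPM), and the stress-induced Sesn1 fell (-0.48). The list missed the threshold with the melanoma sum (984 CPM in IgG, 3405 CPM in anti-Ang2) as a covariate (camera adjusted p = 0.0710), with both sums (0.116) and without anti-Ang2 1, 2 and 3 (0.0516). Its median went to 0.11, 0.09 and 0.16, and the median SE of its genes from 0.17 to 0.22, 0.22 and 0.18. Fbxo32 missed the threshold without IgG 2, 3 or 5 or anti-Ang2 2 or 3 (up to 0.0675), Klf6 without IgG 2, 3 or 4 or anti-Ang2 3 (up to 0.0804), and Sesn1 in 8 of the 10 fits that left out 1 library (up to 0.108). With the melanoma sum Fbxo32 went from 0.80 ± 0.17 to 0.67 ± 0.24 (adjusted p = 0.260), Klf6 from 0.46 ± 0.10 to 0.59 ± 0.13 (0.0789) and Sesn1 from -0.48 ± 0.11 to -0.27 ± 0.14 (0.437). These 3 genes also missed the threshold with the macrophage sum (0.199, 0.170 and 0.289) and without anti-Ang2 1, 2 and 3 (0.200, 0.0874 and 0.260).

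Genes of cell death changed in small number. Of 35 pro-apoptotic genes, 2 rose and 0 fell (adjusted over the list alone, 2 and 0; camera adjusted p = 0.175). Among them was the BH3-only protein Bcl2l11, which rose from 45.9 ± 7.03 to 65.3 ± 7.42 CPM. Bcl2l11 is also in the FOXO list and missed the threshold in 7 of the 10 fits that left out 1 library (up to 0.0955). Its log2 fold change went from 0.51 ± 0.12 to 0.50 ± 0.17 with the melanoma sum (adjusted p = 0.228), 0.64 ± 0.13 with the macrophage sum (0.0617) and 0.61 ± 0.15 without anti-Ang2 1, 2 and 3 (0.0987). Of 15 anti-apoptotic genes, 0 passed by edgeR, over all genes or over the list alone (camera adjusted p = 0.961), and Birc2 had the smallest p (56.5 ± 6.30 and 45.1 ± 4.51 CPM, adjusted p = 0.101). Of 28 p53 target genes, Sesn1 fell and 0 rose (adjusted over the list alone, 1 and 1; camera adjusted p = 0.931).

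Metabolic lists shifted upward with few single genes. In the hypoxia and glycolysis list, 29 of 32 genes had a positive log2 fold change, with a median of 0.42 (camera adjusted p = 0.00011; adjusted p = 0.712 with an estimated correlation). Singly, 1 gene, Adm, rose and 1, the stress-induced mTOR inhibitor Ddit4 (100.1 ± 9.87 to 50.6 ± 8.03 CPM), fell (adjusted over the list alone, 1 and 1). The glycolytic enzyme Eno1 (281 ± 46.5 and 454 ± 156 CPM, adjusted p = 0.118) and the cytokine Mif (29.2 ± 6.65 and 45.6 ± 11.9 CPM, adjusted p = 0.110) did not pass. In the cholesterol synthesis list, 21 of 24 genes had a positive log2 fold change, with a median of 0.36 (camera adjusted p = 0.00086; adjusted p = 0.712 with an estimated correlation). The kinase Pmvk alone passed, lower (-0.38). Adjusted over the list alone, 5 rose and 1 fell. Insig1, a sterol sensor, had 32.9 ± 3.78 and 53.5 ± 14.8 CPM (adjusted p = 0.0679). Of 38 genes of oxidative phosphorylation, 1 rose, the cytochrome oxidase subunit Cox7a2 (85.2 ± 6.06 to 107 ± 5.72 CPM; adjusted over the list alone also 1), with a list median of 0.12 (camera adjusted p = 0.00075). Its adjusted p was 0.579 with an estimated correlation. Beside these lists, the melanoma marker sum was 984 CPM in IgG and 3405 CPM in anti-Ang2, and the macrophage sum 57.6 and 149 CPM. Adding the melanoma sum as a covariate turned the direction of the hypoxia list (median -0.02, camera adjusted p = 0.745) and took the median of the cholesterol list to 0.05 (0.738). The median SE of their genes went from 0.23 to 0.26 and from 0.18 to 0.22. With the macrophage sum the medians were 0.27 (SE 0.29) and 0.23 (SE 0.23), with p of 0.1004 and 0.201. Without anti-Ang2 1, 2 and 3 they were -0.11 (SE 0.18) and 0.03 (SE 0.20), with adjusted p of 0.230 and 0.963 by camera in limma. That of oxidative phosphorylation was 0.10 (SE 0.08 before and 0.11 after, adjusted p = 0.0764 by camera in limma). Pmvk missed the threshold in 9 of the 10 fits that left out 1 library (up to 0.116) and Cox7a2 in 5 (up to 0.0769). With the melanoma sum Pmvk went from -0.38 ± 0.09 to -0.34 ± 0.13 (adjusted p = 0.310) and Cox7a2 from 0.33 ± 0.07 to 0.29 ± 0.10 (0.261). Both also missed it with the macrophage sum (0.129 and 0.205) and without anti-Ang2 1, 2 and 3 (0.261 and 0.233).

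**Figure D3:**
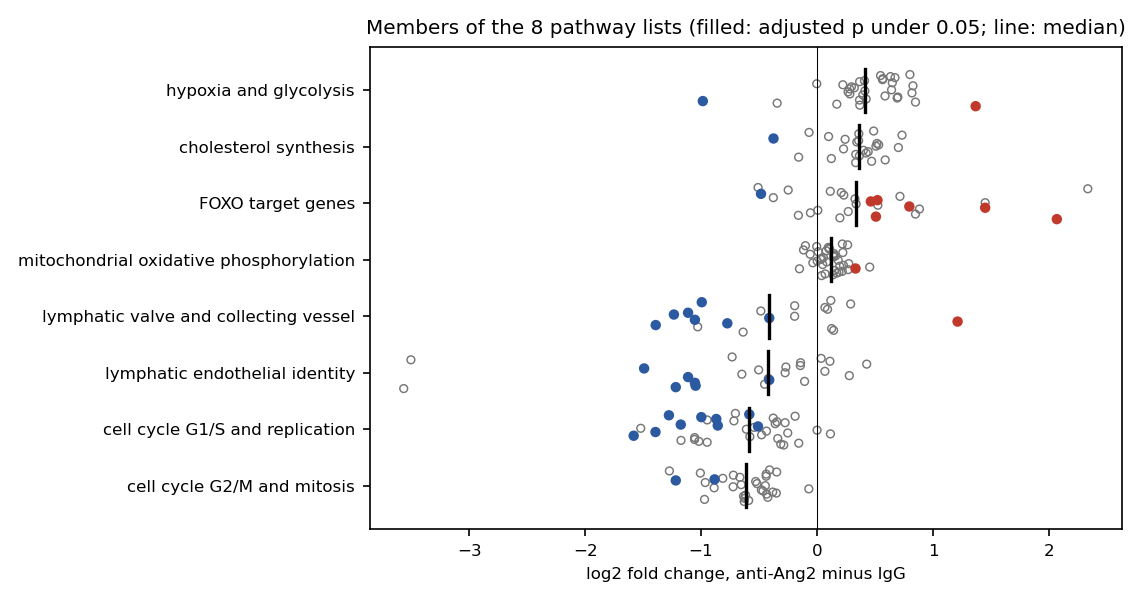
Log2 fold change (anti-Ang2 minus IgG) of the tested genes in each gene list called by camera with a preset correlation, each point a gene, filled where it passed over all genes, with the list median as a vertical line. Median values run from -0.62 for G2/M and mitosis to 0.42 for hypoxia and glycolysis.

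Matrix genes changed in both directions. Of 33 genes of basement membrane and matrix, 2 rose and 4 fell (adjusted over the list alone, 8 and 7; camera adjusted p = 0.931). Fn1 rose, and Eln, fibrillin (Fbn1, 379 ± 33.2 to 179 ± 29.6 CPM) and the endothelial glycoprotein Mmrn2 (530 ± 114 to 240.0 ± 43.4 CPM) fell. Of 20 integrins, 2 fell and 0 rose (adjusted over the list alone, 3 and 3; camera adjusted p = 0.931): Itga9 and the laminin-binding Itga6 (498 ± 39.5 to 360 ± 26.8 CPM). Of 35 focal adhesion genes, 3 fell and 0 rose (adjusted over the list alone, 4 and 0; camera adjusted p = 0.753), the tensin Tns2 (452 ± 75.0 to 229 ± 27.8 CPM), the talin Tln2 (-0.83) and the focal adhesion kinase Ptk2 (-0.36). Among 25 genes of endothelial junctions, 4 fell and 1 rose (adjusted over the list alone, 7 and 2; camera adjusted p = 0.127). The cingulin-like Cgnl1 (130 ± 20.5 to 59.5 ± 8.77 CPM), the adhesion molecule F11r (-0.43) and the connexin Gja4 (-1.23) fell, and the guidance receptor Robo4 rose (0.56). Tln2 missed the threshold without IgG 2 or 5 (up to 0.0687), Ptk2 in 6 and Robo4 in 9 of the 10 fits that left out 1 library (up to 0.0853 and 0.0955). The melanoma sum was 984 CPM in IgG and 3405 CPM in anti-Ang2 libraries. As a covariate it took Itga6 from -0.47 ± 0.08 to -0.46 ± 0.12 (adjusted p = 0.121), Tns2 from -0.98 ± 0.13 to -0.87 ± 0.18 (0.0528), Mmrn2 from -1.14 ± 0.17 to -0.95 ± 0.22 (0.0889) and F11r from -0.43 ± 0.06 to -0.37 ± 0.09 (0.0930), the SE widening more than the effect shrank. Gja4 went from -1.23 ± 0.24 to -0.68 ± 0.20 (0.185), through a smaller effect. Tln2 (to -0.94 ± 0.25, 0.132), Ptk2 (to -0.35 ± 0.12, 0.234) and Robo4 (to 0.69 ± 0.18, 0.127) missed it with SE that were 0.18, 0.08 and 0.13 before. All of these except Tns2 and Mmrn2 missed it with the macrophage sum (0.0596 for Itga6 to 0.218 for Ptk2), and all except Tns2 without anti-Ang2 1, 2 and 3 (0.0530 for Itga6 to 0.174 for Gja4).

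Inflammatory and stress lists gave no call. Of 29 genes of the NF-kB and TNF response, 29 of the type I interferon response and 29 of antigen presentation and interferon gamma response, 0 passed by edgeR, over all genes or over the list alone (camera adjusted p = 0.931, 0.175 and 0.685). The members with the smallest p in the first pair of lists were the inhibitor Nfkbib (46.8 ± 2.36 and 58.7 ± 6.92 CPM, adjusted p = 0.0756) and the interferon-induced Oasl2 (9.15 ± 2.26 and 14.5 ± 4.26 CPM, adjusted p = 0.148). Of 28 genes of leukocyte recruitment, Ccl21a, Icam2 and the scavenging chemokine receptor Ackr3 (340 ± 44.6 to 187 ± 42.8 CPM) fell and 0 rose (adjusted over the list alone, 5 and 1; camera adjusted p = 0.305). In the unfolded protein and integrated stress response list, the pseudokinase Trib3 (0.53) and the glutathione-degrading Chac1 (0.97) rose among 31 genes and 0 fell (adjusted over the list alone, 2 and 0; camera adjusted p = 0.931). Klf6 and the small heat shock protein Hspb1 (0.60) rose among 33 immediate early and heat shock genes and 0 fell (adjusted over the list alone, 5 and 0; camera adjusted p = 0.126). Trib3, Chac1 and Hspb1 missed the threshold in 9, 9 and 8 of the 10 fits that left out 1 library (up to 0.114, 0.125 and 0.130). These 3 also missed it with the melanoma sum (Trib3 0.53 ± 0.13 to 0.60 ± 0.19, Chac1 0.97 ± 0.24 to 0.73 ± 0.35, Hspb1 0.60 ± 0.15 to 0.70 ± 0.22; adjusted p = 0.207, 0.416 and 0.203), with the macrophage sum (0.277, 0.345 and 0.289) and without anti-Ang2 1, 2 and 3 (0.241, 0.337 and 0.303). Ackr3 went from -0.86 ± 0.16 to -0.82 ± 0.21 (adjusted p = 0.121) with the macrophage sum, which was 57.6 CPM in IgG and 149 CPM in anti-Ang2 libraries, and to -1.03 ± 0.22 (0.0671) with the melanoma sum.

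Over the 27 lists, camera with its preset correlation called 4 up and 4 down, and 0 passed with an estimated correlation (limma). The median, mean and camera direction did not share a sign in the lists of integrins, focal adhesion, matrix, NF-kB, unfolded protein response, flow-responsive genes and blood endothelial identity, none of which passed by camera.

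Markers of other tumour cells were present in the sorted libraries, at different levels between mice. The melanoma sum was 441, 1757, 269, 1870 and 580 CPM in the IgG libraries and 5594, 3984, 4590, 1722 and 1136 CPM in the anti-Ang2 libraries. Its geometric mean was 3.88-fold higher after anti-Ang2 (two-sided exact permutation p = 0.0476, adjusted p = 0.171, 3 of 5 anti-Ang2 libraries above all IgG libraries). The pigment enzyme Dct (640 ± 499 and 2113 ± 1210 CPM, adjusted p = 0.143) and Tyrp1 (109 ± 97.5 and 450 ± 267 CPM, adjusted p = 0.126) did not pass. The melanosome protein Pmel did (51.4 ± 36.8 to 250 ± 142 CPM, adjusted p = 0.0496 by edgeR). By camera the 12 melanoma markers were higher (adjusted p = 3.7e-07; 1 rose over all genes and 9 adjusted over the list alone), and so were the 11 tested macrophage markers (adjusted p = 5.9e-05; 0 and 0). With an estimated correlation the adjusted p was 0.364 for either list. The exact permutation p of the macrophage sum was 0.0635, with Lyz2 at 22.9 ± 34.8 and 62.4 ± 42.1 CPM, C1qb at 4.26 ± 6.16 and 19.7 ± 12.4 CPM and Cd68 at 13.8 ± 7.15 and 16.2 ± 7.14 CPM. Its exact p was 0.0159 without IgG 1 and 0.0317 without anti-Ang2 5. The pericyte and smooth muscle sum was 151 ± 65.2 and 324 ± 106 CPM (exact permutation p = 0.0317, adjusted p = 0.171). Kcnj8 rose (23.4 ± 6.20 to 62.3 ± 16.3 CPM). Its log2 fold change of 1.41 ± 0.23 went to 1.23 ± 0.33 with the melanoma sum (adjusted p = 0.134), 1.14 ± 0.26 with the macrophage sum (0.0821) and 1.35 ± 0.32 without anti-Ang2 1, 2 and 3 (0.0874), where it did not pass. Cspg4 (53.2 ± 40.0 and 172 ± 91.1 CPM, adjusted p = 0.127) and Acta2 (31.3 ± 12.7 and 39.8 ± 18.6 CPM, adjusted p = 0.709) did not pass. By camera the pericyte list did not pass (adjusted p = 0.307), with 5 tested members positive, 5 negative and a median log2 fold change of 0.06. Cspg4, its most abundant tested member, was 17.0, 104, 17.8, 86.1 and 41.1 CPM in the IgG libraries. In the anti-Ang2 libraries it was 274, 203, 231, 89.8 and 64.4 CPM, highest in anti-Ang2 1, 2 and 3, as was the melanoma sum. A rise of pericyte RNA cannot be told apart from melanoma RNA by this sum. The fibroblast sum was 480 ± 309 and 469 ± 230 CPM (exact permutation p = 0.881; camera adjusted p = 0.783). Its main members were Dcn at 144 and 332 CPM, Col3a1 at 127 and 41.2 CPM and Col1a1 at 91.9 and 22.7 CPM, none of which passed. Of 9 tested members, 3 had a positive and 6 a negative log2 fold change, and 1 was called lower by edgeR. The melanoma difference had an exact permutation p of 0.0714 to 0.0794 without IgG 1, 3 or 5 or anti-Ang2 1, 2 or 3, and the pericyte difference 0.0635 without IgG 3 or anti-Ang2 1, 2, 3 or 4. Pmel missed the threshold in 7 of the 10 fits that left out 1 library (up to 0.119). Its log2 fold change was 2.28 ± 0.57, and 2.06 ± 0.85 with the macrophage sum as a covariate (adjusted p = 0.382), 1.02 ± 0.63 without anti-Ang2 1, 2 and 3 (0.466) and 0.61 ± 0.23 with the melanoma sum (0.288), of which it is a part.

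**Figure D4:**
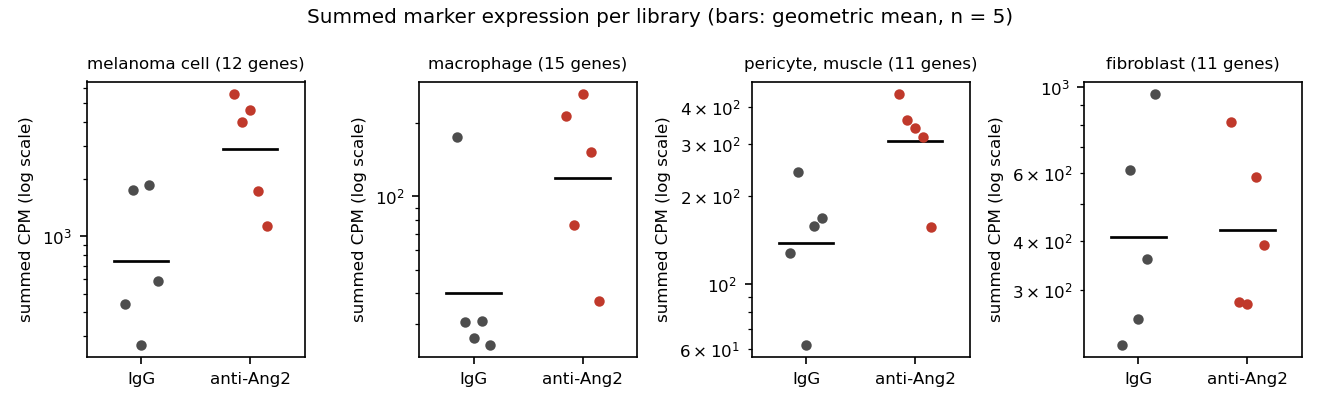
Summed CPM of marker genes per library on a log scale for melanoma cells, macrophages, pericytes and smooth muscle, and fibroblasts, with the geometric mean of each group as a bar (n = 5). Melanoma sums were 269 to 1870 CPM in IgG libraries and 1136 to 5594 CPM in anti-Ang2 libraries.

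The other marker sums were low or similar between the groups. Dendritic cell markers summed to 463 ± 43.5 and 453 ± 88.9 CPM (exact permutation p = 0.889; camera adjusted p = 0.783), most of it from the actin-bundling Fscn1 (364 and 399 CPM, adjusted p = 0.715). The transcription factor Zbtb46 fell (94.6 ± 29.1 to 48.5 ± 7.00 CPM, adjusted p = 0.0138 by edgeR). Its log2 fold change of -0.97 ± 0.19 went to -0.83 ± 0.26 with the melanoma sum (adjusted p = 0.201), -0.89 ± 0.26 with the macrophage sum (0.186) and -0.97 ± 0.30 without anti-Ang2 1, 2 and 3 (0.158), where it did not pass. Fscn1 and Zbtb46 made up most of the dendritic cell sum, and the next tested marker had at most 3.37 CPM in any library. That sum is therefore a weak measure of dendritic cell RNA. The cell type in which Zbtb46 fell was not tested. T and NK cell markers summed to 32.8 and 23.4 CPM (exact permutation p = 0.0714; camera adjusted p = 0.119) and neutrophil markers to 45.9 and 45.1 CPM (p = 0.881, exact). Most of the neutrophil sum came from a single marker, so that it is a weak measure of neutrophil RNA. Keratinocyte (5.01 and 4.06 CPM, exact permutation p = 0.373), B cell (3.93 and 3.15, p = 0.857), erythroid (3.78 and 2.07, p = 0.667) and skeletal muscle markers (2.09 and 2.55, p = 0.667) were near the floor. Adipocyte markers, 3 genes also near the floor, summed to 2.66 ± 0.54 and 1.65 ± 0.34 CPM. They had the smallest exact permutation p that 5 against 5 libraries allow (0.00794, adjusted p = 0.0952). No mesothelial marker passed the filter on low counts. After adjustment over the 12 lists with a sum, 0 of these exact tests passed and 3 had an unadjusted p under 0.05. A single list at the smallest possible exact permutation p cannot pass that adjustment, as the adipocyte sum shows.

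Outside rows with a repeated symbol, the authors' deposited table held 779 genes higher and 887 lower at an adjusted p under 0.05. All 671 genes called here were also called in the authors' deposited table with the same sign. Of the deposited calls 1599 were tested here, all with the same sign, and 671 of them were called here. Both tests start from the same counts, so that the shared signs are no independent support. The log2 fold changes in the authors' deposited table were 2.03 for Angpt2, -1.26 for Tek, -0.47 for Tie1, -2.40 for Eln, 1.17 for Fn1 and -4.23 for Postn.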

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

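Of the tests in this part, the comparison with endothelial junction genes and the exact permutation of list means were chosen only after the result was seen, and the correlations with marker sums were planned after the fits with those sums as covariates had been seen.

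Genes higher after anti-Ang2 numbered 217, while the melanoma and macrophage marker sums rose 3.88-fold and 2.97-fold. RNA of melanoma cells or macrophages carried over in the sort could add to the higher genes. With group means removed, the median correlation of the higher genes with the melanoma sum was 0.207 (216 genes, one-sided permutation p = 0.041, all genes 0.0167) and with the macrophage sum 0.176 (217 genes, permutation p = 0.029, all genes 0.0057), both below the 0.3 set beforehand as a sign of carry-over and above 0, so that carried-over RNA and a response of LEC cannot be told apart for these genes. With the melanoma sum as a covariate the median log2 fold change of the 217 genes went from 0.82 (median SE 0.16) to 0.67 (0.21), so that smaller effects and wider errors both ended calls. A response of LEC to Ang2 inhibition stays open.

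The cell cycle lists had a median log2 fold change of -0.60 over 66 genes, and were called by camera with its preset correlation but not with an estimated correlation (adjusted p = 0.205 for G1/S and 0.579 for G2/M). A lower share of endothelial cells among the sorted cells would lower junction genes alike, but their median was -0.0612, above the cell cycle median (95% bootstrap interval over genes -0.29 to 0.11). The lymphatic identity and valve lists had medians of -0.42 and -0.41. That of blood endothelial identity was -0.05, with 11 genes positive and 11 negative. Prox1 and Lyve1, chosen after their values were seen, did not pass by edgeR. These values do not settle whether the share of LEC among the sorted endothelial cells was lower, which stays open. GC content and transcript length do not account for the fall: after subtracting the trend with both, the median was -0.632 (interval over genes -0.74 to -0.50). Both intervals resample genes and leave out the spread between mice. With the melanoma or the macrophage sum as a covariate the median was -0.59 or -0.63 and the median SE went from 0.26 to 0.35 or 0.33, and a part of either cell type in the fall stays open. A lower share of dividing LEC after Ang2 inhibition may underlie the fall, as a hypothesis drawn from the same libraries without a test of its own. Dividing cells of other types were not tested for either.

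The hypoxia and glycolysis list had a median of 0.42, called by camera with its preset correlation but not with an estimated correlation (adjusted p = 0.712) nor by the exact permutation of list means (p = 0.167, adjusted 0.5). Melanoma cell RNA is a candidate source: with group means removed, the median correlation of its 32 genes with the melanoma sum was 0.619 (permutation p = 0.028), and with the sum as a covariate the median went to -0.02. The correlation with the macrophage sum was 0.338 (permutation p = 0.163), which decides nothing with 10 libraries. The sort should have removed melanoma cells, whose most abundant marker was Dct at 640 CPM in IgG and 2113 CPM in anti-Ang2 libraries. A response of glycolytic genes in LEC themselves stays open.

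A single library stood far from the other 4 of its group in 22 of 254 groups of values (8.66%), where chance gives about 1 in 20. Among IgG libraries, IgG 1 was highest for the macrophage sum (175.9 CPM against at most 30.8), Lyz2 (85.08 CPM), C1qb (15.18 CPM) and Lyve1 (5244 CPM) and lowest for Cmah (181.5 CPM) and Thsd4 (56.59 CPM). IgG 2 was highest in depth (83.85 M counts) and genes detected (21130), IgG 3 in the erythroid sum (12.05 CPM), IgG 4 in the B cell sum (13.16 CPM) and Birc2 (67.5 CPM), and IgG 5 was lowest in rRNA genes (0.3186%). Among anti-Ang2 libraries, anti-Ang2 5 was lowest in depth (38.09 M counts), the dendritic cell sum (297.4 CPM) and Fscn1 (255 CPM) and highest for Foxc2 (172.7 CPM) and the skeletal muscle sum (5.334 CPM). Anti-Ang2 2 was highest for Tie1 (1196 CPM) and Lynx1 (13.68 CPM), anti-Ang2 1 lowest for Lyve1 (4305 CPM) and Igf1r (29.25 CPM), and anti-Ang2 3 lowest for Fam49a (68.86 CPM).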

How the results depend on the processing

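The fits with both marker sums, without anti-Ang2 1, 2 and 3 and the exact permutation of list means were chosen only after the data were seen. The fit without anti-Ang2 1, 2 and 3 keeps only anti-Ang2 4 and 5 beside the IgG libraries.

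Against 217 genes higher and 454 lower, DESeq2 called 810 and 880, quality weights 670 and 780, an adjusted p under 0.10 gave 505 and 718, the macrophage covariate 28 and 114, the melanoma covariate 24 and 91, removal of anti-Ang2 1, 2 and 3 gave 55 and 178, and both covariates 0 and 0 by edgeR (880 and 974 at an unadjusted p under 0.05; no other tool was run with both). All 671 calls kept their sign wherever they were tested. With both covariates the median log2 fold change of higher genes went from 0.82 (median SE 0.16) to 0.62 (0.20) and of lower genes from -0.81 (0.14) to -0.70 (0.20), so that calls ended through wider errors as well as smaller effects. Voom, the other normalizations, filters and robust dispersion stayed within 1.5 times. Leaving out 1 library gave 82 to 326 higher and 259 to 468 lower, fewer samples being part of the cause.

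With the replicate number of the sample titles as a block (replicate block) 82 were higher and 268 lower. These numbers do not pair the libraries: correlations of deviations between equal numbers were -0.125, 0.113, -0.113, -0.0858 and -0.0417, and no library correlated best with its own number. The sample descriptions carry other numbers, with none shared by the groups, so that they pair nothing.

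Of 27 gene lists 8 were called, against 4 without anti-Ang2 1, 2 and 3, 0 with an estimated correlation (limma) and 0 with the exact permutation (smallest adjusted p 0.0714, with 7 lists under 0.05 unadjusted). The exact permutation p of 5 against 5 libraries cannot go below 0.00794. After adjustment over 27 lists it could therefore hardly pass, and its 0 decides little. All 8 lists called by camera passed in each of the 10 fits without 1 library. Direction turned for hypoxia with the melanoma covariate (adjusted p = 0.745), both covariates (0.191) and without anti-Ang2 1, 2 and 3 (0.230), and for cholesterol synthesis with both covariates (0.496). Of 12 cell type marker sums, 3 had an unadjusted exact permutation p under 0.05 (0 adjusted), and 1 to 4 without 1 library (1 without IgG 3 or anti-Ang2 1, 2 or 3).

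Among genes that did not pass, log2 fold changes turned sign with the macrophage covariate for Lyz2 (-0.0052), Cd68 (-0.49) and Acta2 (-0.15), with the melanoma covariate for Dct (-0.11), Cd68 (-0.025) and Fscn1 (-0.13), with both for Eno1 (-0.026), Dct (-0.16), Cd68 (-0.55), Acta2 (-0.28), Fscn1 (-0.21) and Prox1 (0.018), and without anti-Ang2 1, 2 and 3 for Cd68 (-0.54) and Fscn1 (-0.13). Of 91 called genes named in the text, 66 passed without any 1 library, 40 with the melanoma covariate, 44 with the macrophage covariate and 45 without anti-Ang2 1, 2 and 3. Beyond the stated parts, the cause was not tested. The depth was at least 38090933 counts per library. These counts may include copies from the amplification of 0.5 ng of RNA, as reads carry no molecular identifiers. How far this limits the results was not tested.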

Other observations

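Of the tests in this part, the exact permutation of list means was chosen only after the list result was seen, and the genes of the next paragraphs were chosen after their values were seen.

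Besides the members of the gene lists, 6 single genes of matrix-associated proteins fell after anti-Ang2 (edgeR, n = 5 per group). They were picked by their values and not tested as a list. The microfibril protein Mfap2 (log2 fold change -2.24, adjusted p = 0.0030), the fibulin Fbln2 (-1.35, adjusted p = 0.0011), the fibrillin-binding Thsd4 (-1.38, adjusted p = 0.0014), the proteoglycan Bgn (-1.08, adjusted p = 0.0121) and the matrix protease Tll1 (-2.31, adjusted p = 0.0011) were lower, and the matrix-bound growth factor binding protein Igfbp5 fell from 1109 to 129 CPM (-3.10, adjusted p = 0.0012). With the melanoma covariate Bgn went from -1.08 ± 0.20 to -0.86 ± 0.26 (adjusted p = 0.189), while the other 5 passed. With the macrophage covariate Mfap2 went from -2.24 ± 0.32 to -1.63 ± 0.34 (0.0642) and Bgn to -0.92 ± 0.24 (0.129). Without anti-Ang2 1, 2 and 3 Mfap2 (-1.83 ± 0.42, 0.0849), Thsd4 (-1.38 ± 0.17 to -1.31 ± 0.27, 0.0630) and Bgn (-0.81 ± 0.21, 0.105) missed the threshold.

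Dual oxidase Duox2 (-2.47, adjusted p = 0.0012) fell with its partner Duoxa2, and Wnt2 (-2.99, adjusted p = 0.0032) and Wnt5a (-1.87, adjusted p = 0.0184) fell. The 10 tested genes of the Wnt stem were not called as a family (median 0.10, 6 positive, 2 lower, camera adjusted p = 0.464). Higher were the receptor kinase Kit (1.67, adjusted p = 0.0078), the chemokine receptor Cxcr4 (1.20, adjusted p = 0.0316), the matricellular Thbs1 (2221 to 4883 CPM, 1.14, adjusted p = 0.0121) and the ankyrin repeat protein Ankrd1 (1.75, adjusted p = 0.0205). Wnt5a missed the threshold without IgG 2, IgG 3 or anti-Ang2 3 (up to 0.0576), Ankrd1 without IgG 2, 3, 4 or 5 or anti-Ang2 3 (up to 0.0668) and Cxcr4 in 7 of the 10 fits without 1 library (up to 0.0751). The melanoma covariate ended the calls of Wnt5a (-1.87 ± 0.38 to -1.62 ± 0.48, adjusted p = 0.178), Cxcr4 (1.20 ± 0.27 to 1.07 ± 0.36, 0.238), Thbs1 (1.14 ± 0.21 to 1.33 ± 0.30, 0.0747) and Ankrd1 (1.75 ± 0.36 to 1.79 ± 0.58, 0.213), mainly as the SE widened, and that of Kit (1.67 ± 0.29 to 0.97 ± 0.26, 0.139) as the effect shrank. These 5 also missed the threshold with the macrophage covariate (0.0921 for Thbs1 to 0.251 for Cxcr4, with Ankrd1 at 1.06 ± 0.33, 0.213) and without anti-Ang2 1, 2 and 3 (0.0856 for Thbs1 to 0.205 for Wnt5a). Wnt2 missed it in both (-2.99 ± 0.44 to -2.53 ± 0.59, 0.0882, and -2.77 ± 0.71, 0.105).

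As a hypothesis, lower Tie2 signalling may release FOXO transcription factors. Without Angpt2 and Esm1, the remaining 24 FOXO target genes had a median log2 fold change of 0.30 and a camera p of 0.0011 with the preset correlation and 0.0446 with an estimated correlation, both unadjusted, which meets the prediction. The full list had an adjusted p of 0.205 with an estimated correlation and 0.0710 with the melanoma covariate, where its median went from 0.33 to 0.11, and Tie2 signalling itself was not measured.

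Among 156 families of at least 10 genes sharing a symbol stem, 1 was called by camera, the Mcm family (10 genes, 3 lower, median -0.51, adjusted p = 0.0062), and 0 passed with an estimated correlation (Mcm adjusted p = 0.898).

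Chance is an unlikely source of the count of genes: of 100 splits of the 10 libraries into 5 and 5, the real one included, 1 gave as many as 671 calls, the highest other being 2. The smallest share that this comparison can give is 1 in 100. Each other split mixes treated and control libraries in both groups, which widens the spread within them and lowers their calls. By camera with its preset correlation, 24 of 100 splits called at least 8 pathway lists (highest other 13). At least 2 cell type lists were called in 49 of 100 (highest other 4). Chance is thus not excluded for the called lists, but these shares are no rate of chance. Some of the other splits keep part of the treatment difference. That with 13 pathway lists exchanged only IgG 5 and anti-Ang2 5. With the exact permutation of list means, G1/S, lymphatic identity and valve lists had the smallest p possible (0.00794, adjusted 0.0714). Oxidative phosphorylation had 0.0159 (adjusted 0.0857), as had the pro-apoptotic list, not called by camera. G2/M and FOXO had 0.0397 (adjusted 0.153), cholesterol synthesis 0.127 (adjusted 0.429) and hypoxia 0.167 (adjusted 0.5) by the same exact test.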
